A study of Rattus norvegicus with 12 samples.

How the data were processed

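RNA-seq was done on 12 samples from 2 rat cell lines, NRK-52E kidney epithelial cells and NRK-49F kidney fibroblasts. Per the labels' protocols, both were kept in DMEM with 5% FBS, and NRK-52E received cisplatin or vehicle at 50% confluence. The protocol gives 6 h of exposure, a rinse, and 24 h in fresh medium, which became the conditioned medium, whereas the series design text gives 24 h of treatment with 40 µM cisplatin or vehicle. Which of these times applies to the sequenced NRK-52E cells is not settled by the labels. NRK-49F was cultured in the conditioned media for 24 h, per the design text. RNA was extracted with TRIzol and Direct-zol columns, and libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols.

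The authors deposited one table of raw read counts per Ensembl rat gene with a column for each sample. The values are whole numbers whose totals differ between samples, so they were treated as counts with no normalization. STAR 2.7.10a, featureCounts and Subread are named in the submitters' processing notes, without their roles or settings. The genome build, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes may have been counted together, and genes with near-identical copies may have lost or shared reads, so counts of single genes of these kinds are uncertain. The table holds 21698 genes, of which 209 had 0 counts in all 12 libraries, and each column was assigned by its name, which is a sample title.

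Samples were grouped by line and treatment as labelled, with 3 libraries in each of 4 groups. Total counts ranged from 9684887 to 12549675, and 3 counts, used as the floor for a count of 0, equal 0.239 to 0.31 CPM in a single library. The fold of a gene with 0 counts in a whole group was bounded by 3 counts over the group. The floors cover counting error only, whereas bootstrap intervals of median log2 fold changes (2000 resamples) and the exact binomial interval of a share of genes are over genes. Replicates were first compared for duplicated libraries: a chi-square statistic of the counts over genes was 1.707 to 4.09 per degree of freedom within groups, above sampling noise for every pair, so each library counted as 1 sample.

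Each line was tested apart with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group (minimum count 10, minimum total 15), TMM factors, glmQLFit and glmQLFTest on the group alone, and Benjamini-Hochberg adjustment at a threshold of 0.05. TMM factors were 0.983 to 0.987 for NRK-52E vehicle, 1.013 to 1.016 for NRK-52E cisplatin, 0.930 to 0.934 for NRK-49F with untreated medium and 1.068 to 1.075 for NRK-49F with cisplatin medium. The difference of the 2 responses was a contrast of 4 group means in one fit of all 12 libraries. Genes called in both lines were counted by direction beside the number expected of independent lists. CPM values of single genes use TMM-scaled library sizes, and standard errors are the absolute log2 fold change divided by the square root of the F statistic. Principal components were computed on log2 CPM with a prior count of 2. Counts of detected genes were repeated on libraries thinned to 9684887 counts, as the mean of 20 draws. Shares and numbers of detected genes were compared by exact two-sided permutation tests, whose smallest p with 3 libraries against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

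Single genes to be named were to be a fixed panel, members of 28 fixed gene lists, and the genes with the most extreme log2 fold changes on each side. The latter had to have an adjusted p below 0.05, a mean of at least 2 CPM, no overlap between the groups and a gene symbol. The files do not pair identifiers with names, and the table of rat RefSeq genes (GRCr8) matched 0 of the 21698 identifiers. The panels, the 28 lists, their set tests and the shares of mitochondrial and ribosomal protein genes were therefore not run. The last part of the rule was applied without its symbol condition, and 1 gene on each side per line is given. Without that condition, 8306 genes in NRK-52E and 6570 in NRK-49F passed the rule. The groups did not overlap for 77.6% of genes in NRK-52E and 65.1% in NRK-49F, where chance gives 10%.

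The edgeR steps were tested on simulated data drawn from the real control-group means and library sizes. They held 200 changed genes, 50 per fold size, and a biological coefficient of variation of 0.04 for every gene. For NRK-52E (11735 genes), 66% of genes changed by 1.25-fold were recovered, 86% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, with 12 false calls (6.4% of calls). For NRK-49F (11373 genes) the shares were 52%, 90%, 96% and 100%, with 6 false calls (3.4%). For the contrast (12486 genes) they were 40%, 64%, 90% and 92%, with 3 false calls (2.1%). Nearly all simulated genes were unchanged, whereas 76.2% of tested genes were called in NRK-52E and 61.8% in NRK-49F. The simulation therefore did not test the TMM scaling where most genes change, and its rates need not hold for the real comparisons.

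Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE factors, library size only, no filter, at least 50 counts in 3 libraries, removal of the 10 most abundant genes, the replicate number as a block, stricter thresholds, one fit of all 12 libraries, and each library left out in turn. Alternatives for the number of detected genes, for the correlation of the responses and for genes with opposite directions were added after seeing the data.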

Results

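RNA-seq gene counts were analysed for 2 rat kidney cell lines, NRK-52E, an epithelial line used as a model of the kidney tubule, and NRK-49F, a kidney fibroblast line. NRK-52E cells had received cisplatin, a platinum drug that crosslinks DNA and injures tubular cells, at 40 µM, or vehicle. NRK-49F cells had been grown in medium conditioned by NRK-52E cells that were either untreated or treated with 40 µM cisplatin, called untreated medium and cisplatin medium here. Each of the 4 groups held 3 libraries, 12 in all. Total counts were 11734140, 11339313 and 12468005 in the NRK-52E vehicle libraries and 11580499, 11435842 and 9684887 in the NRK-52E cisplatin libraries. They were 12090151, 10411214 and 11417355 in NRK-49F with untreated medium and 10718789, 12010763 and 12549675 in NRK-49F with cisplatin medium. A floor of 3 counts in a single library corresponded to 0.239 to 0.31 CPM (counts scaled to the library total), a limit that covers counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

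The labelled lines and treatments accounted for most of the variation among libraries. The first principal component of log2 CPM over 13127 genes held 80.1% of the variance and separated the lines. The second held 13.8% and separated NRK-52E vehicle libraries, with scores of 61.68 to 62.19, from cisplatin libraries, with scores of -63.75 to -58.08. NRK-49F libraries moved along the first component toward NRK-52E, from scores of -114.07 to -113.13 in untreated medium to -98.8 to -96.84 in cisplatin medium. The gap between the NRK-49F groups was wider on the third component, which held 3.2% of the variance. Scores there were 27.31 to 29.44 in untreated medium and -31.64 to -30.05 in cisplatin medium. Spearman correlations across genes, which are not independent replicates, moved the same way. The mean correlation of NRK-52E vehicle libraries with NRK-49F libraries was 0.808 (range 0.807 to 0.809 over 9 pairs) for untreated medium and 0.842 (0.84 to 0.843 over 9 pairs) for cisplatin medium. For NRK-52E cisplatin libraries the mean correlation moved less, from 0.814 to 0.832. Between the groups of one line it was 0.939 in NRK-52E and 0.98 in NRK-49F.

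**Figure D1:**
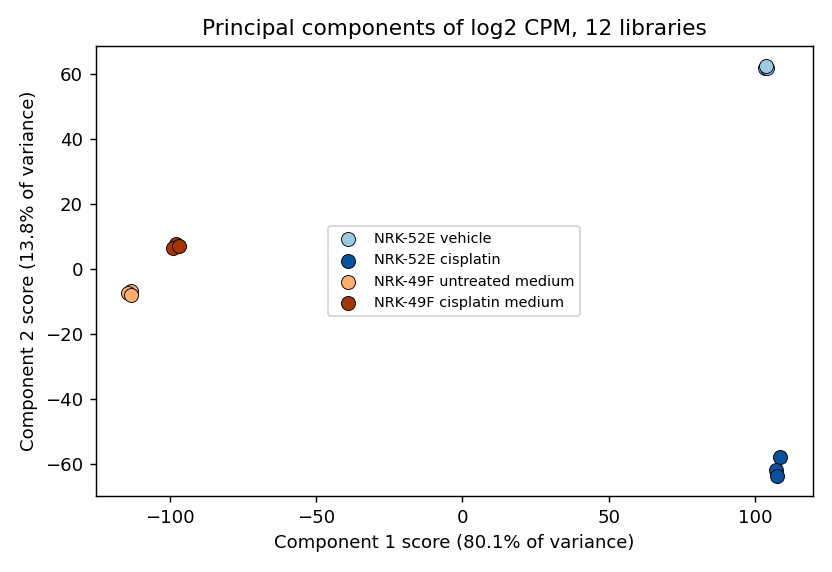
Scores of the 12 libraries on the first 2 principal components of log2 CPM (unitless scores, with the share of variance on each axis), 1 point per library and 1 colour per group. The lines lie at opposite ends of component 1, NRK-52E vehicle and cisplatin libraries lie apart on component 2, and NRK-49F libraries in cisplatin medium lie nearer to NRK-52E on component 1 (-98.8 to -96.84) than those in untreated medium (-114.07 to -113.13).

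The first comparison asked how cisplatin changed the transcriptome of the epithelial cells. Of 12508 genes tested in NRK-52E, 4837 rose and 4699 fell with cisplatin, and 2972 did not pass the test. Large changes were mostly increases: 1822 genes rose and 973 fell by at least 2-fold, 896 rose and 148 fell by at least 4-fold, and 310 rose and 8 fell by at least 16-fold. The median log2 fold change was 0.71 among genes that rose and -0.56 among genes that fell. The share of genes that rose was highest in the class of lowest abundance and the share that fell in the class of highest abundance. Among 419 genes with a mean under 1 CPM, 248 rose (59.2%) and 31 fell (7.4%), and among 2945 genes of 1 to 10 CPM, 1251 rose and 689 fell. A gene with a mean under 1 CPM passed the filter more readily when 1 group was clearly higher, and 243 of those 248 rose at least 2-fold. The shares in the class under 1 CPM are thus partly set by the filter. Among 2520 genes of 100 CPM or more, 889 rose (35.3%) and 1251 fell (49.6%). Between 10 and 100 CPM, where 6624 genes were tested, 2449 rose and 2728 fell, and this order turned to 2648 and 2548 when counts were scaled by library size only. Most of the excess of 2-fold increases came from genes under 10 CPM. Changes of at least 2-fold were 243 increases and 26 decreases under 1 CPM, and 887 and 318 at 1 to 10 CPM. They were 525 and 485 at 10 to 100 CPM, and 167 and 144 at 100 CPM or more. Genes that fell held 57.0% ± 0.14 of the counts in vehicle libraries and 39.9% ± 0.43 in cisplatin libraries, and genes that rose held 27.0% ± 0.12 and 43.6% ± 0.40 (SD, n = 3 each). Both sets were chosen by their change in these libraries, so only the size of these shares is informative, not their direction.

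More genes were detected in NRK-52E after cisplatin. Genes with at least 1 count numbered 15812 ± 83.5 in vehicle libraries and 17980 ± 197 in cisplatin libraries (SD, n = 3 each), a gain of 2168. The gain was 1258 for genes with at least 5 counts. With every library thinned to the total of the smallest, 9684887 counts, the numbers were 15510 ± 19.7 and 17761 ± 120, a gain of 2251. Each cisplatin library lay above each vehicle library in the unthinned and thinned numbers. The exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 libraries against 3 allow. A group of 94 genes had at most 3 counts over the 3 vehicle libraries together and at least 2 CPM with cisplatin. All 94 passed the edgeR test, which this choice of genes all but ensured, so the pass is no separate support. Their median level with cisplatin was 3.23 CPM and the highest 32.9 CPM, and 25 of them had 0 counts in all vehicle libraries. In NRK-49F with untreated medium, 71 of these 94 genes were also at or under 3 counts and 9 were at 2 CPM or more. The reverse, a gene at 2 CPM or more with vehicle and at most 3 counts with cisplatin, was found for 3 genes.

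**Figure D2:**
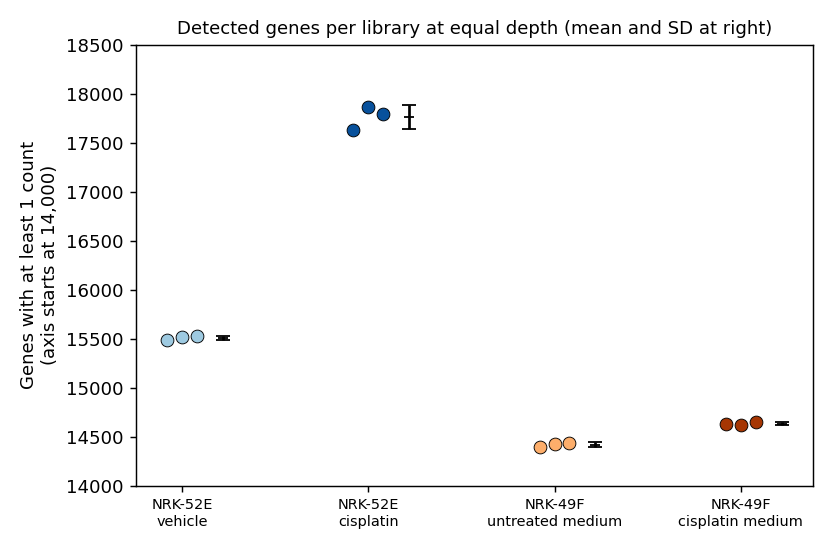
Genes with at least 1 count in each library after thinning to 9684887 counts (vertical axis, number of genes, starting at 14,000), with 1 point per library and the group mean ± SD to the right of the points (n = 3). NRK-52E cisplatin libraries lie at 17629 to 17863 genes and vehicle libraries at 15487 to 15523, while the NRK-49F groups differ by 215 genes on average.

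The files do not pair the gene identifiers with gene names, so single genes are given by Ensembl identifier, and no gene family or pathway is described. ENSRNOG00000046643 had 0 counts in all 3 NRK-52E vehicle libraries and 92, 142 and 114 counts in the cisplatin libraries, or 10.6 ± 2.39 CPM (SD, n = 3). From counts pooled over each group, that is at least 122-fold higher than a floor of 3 counts over the 3 vehicle libraries together, which equals 0.0857 CPM (edgeR adjusted p = 1.5e-17). ENSRNOG00000062503 fell from 64.1 ± 0.677 to 2.42 ± 0.776 CPM (SD, n = 3 each), a log2 fold change of -4.69 with a standard error of 0.12 (edgeR adjusted p = 4.41e-28).

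All these calls came from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, which 76.2% of the tested genes passed. The common biological coefficient of variation, as edgeR terms it, was 3.76% between these libraries, which may be technical replicates. The share that passed therefore need not hold for new cultures. Small changes passed as well: with a required absolute log2 fold change of 1 the count was 2795, and with a test against a 1.5-fold change it was 3883.

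The second comparison, which the design text sets up to examine paracrine effects of epithelial cells on fibroblasts, was of NRK-49F in the conditioned media. Of 11525 genes tested in NRK-49F, 3555 rose and 3568 fell in cisplatin medium compared with untreated medium, and 4402 did not pass the test. Changes of at least 2-fold comprised 404 increases and 382 decreases. At 4-fold or more there were 27 increases and 71 decreases, and at 16-fold or more 12 genes fell and 0 rose. The median log2 fold change was 0.47 among genes that rose and -0.38 among genes that fell. Among 2093 genes of 100 CPM or more, 1259 fell (60.2%) and 362 rose (17.3%), but with library size as the only scaling 862 rose and 651 fell. Among 2763 genes of 1 to 10 CPM, 940 rose (34.0%) and 289 fell (10.5%), an order that held with library size only (1367 and 188). The 6456 genes between 10 and 100 CPM comprised 2228 that rose and 1997 that fell, or 3654 and 1068 with library size only. The 213 genes under 1 CPM comprised 25 that rose and 23 that fell, or 35 and 19 with library size only. Changes of at least 2-fold, counted with TMM factors, were not balanced within the classes. They were 19 increases and 20 decreases under 1 CPM, and 252 and 111 at 1 to 10 CPM. At 10 to 100 CPM they were 128 and 151, and at 100 CPM or more 5 and 100.

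The 10 most abundant genes held 10.7% ± 0.10 of the counts in untreated medium and 9.42% ± 0.20 in cisplatin medium (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). In NRK-52E the share was 4.07% ± 0.04 with vehicle and 4.52% ± 0.24 with cisplatin (SD, n = 3 each, exact two-sided permutation p = 0.1). The number of detected genes in NRK-49F was 14607 ± 79.8 in untreated and 14873 ± 111 in cisplatin medium (SD, n = 3 each, exact two-sided permutation p = 0.1). No gene went from at most 3 counts over a group to 2 CPM or more, or the reverse.

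ENSRNOG00000009726 rose in NRK-49F from 0.613 ± 0.239 CPM in untreated medium to 6.79 ± 1.45 CPM in cisplatin medium (SD, n = 3 each), a log2 fold change of 3.47 with a standard error of 0.28 (edgeR adjusted p = 6.28e-13). ENSRNOG00000057443 fell from 52.2 ± 2.74 to 0.712 ± 0.131 CPM (SD, n = 3 each), a log2 fold change of -6.17 with a standard error of 0.14 (edgeR adjusted p = 6.91e-29). Both were nearly undetected in NRK-52E, with 0 counts over the vehicle libraries and 1 and 4 counts, respectively, over the cisplatin libraries.

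The edgeR test called 61.8% of the tested genes, at a biological coefficient of variation of 3.47%, again between libraries that may be technical replicates. The count fell to 786 with a required absolute log2 fold change of 1 and to 1184 with the test against 1.5-fold. The even split of directions rests on the scaling: with library size only, the median log2 fold change of all genes moved by 0.20, and 5918 genes rose and 1926 fell, so directions in NRK-49F are relative to the bulk of its genes as set by the TMM factors.

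**Figure D3:**
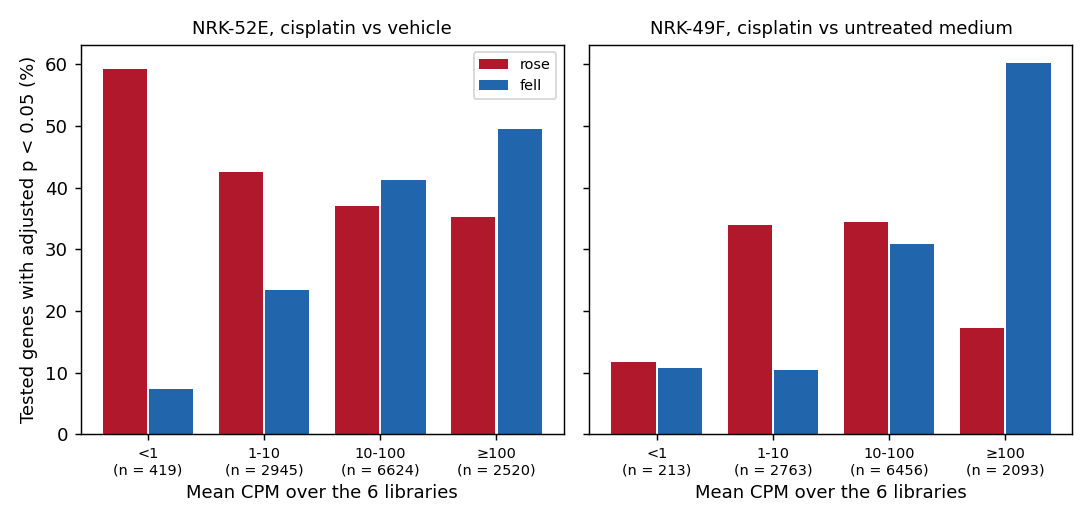
Percent of tested genes that rose (red bars) or fell (blue bars) at edgeR adjusted p below 0.05, by mean CPM over the 6 libraries of a line (horizontal axis, with the number of genes per class), for NRK-52E on the left and NRK-49F on the right. Decreases outnumber increases at 100 CPM or more in both lines (49.6% and 60.2% fell), an order that library size scaling turns in NRK-49F, as it does for NRK-52E genes between 10 and 100 CPM.

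The 2 responses were then compared, first gene by gene. Among 10937 genes tested in both lines, 5465 passed the test in both, and most of these moved in opposite directions. With cisplatin in NRK-52E and cisplatin medium in NRK-49F, 1694 genes rose in NRK-52E and fell in NRK-49F, and 1917 fell in NRK-52E and rose in NRK-49F. Together these were 3611 genes (66.1%). Another 851 genes rose in both lines and 1003 fell in both. Independent lists of these sizes would share 1226 and 1376 genes in the opposite directions, 1228 genes that rose in both and 1373 that fell in both. Across the 10937 genes the log2 fold changes had a Pearson correlation of -0.254 and a Spearman correlation of -0.274, where genes are not independent replicates. The Pearson value was -0.068 with no filter on low counts. The comparisons shared no library. Of the 280 genes that changed by at least 2-fold in both lines, 124 rose in NRK-52E and fell in NRK-49F, 87 did the reverse, 48 rose in both and 21 fell in both.

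With library size as the only scaling, 3831 of 5951 genes called in both lines moved in opposite directions (64.4%), with the classes redistributed. Genes that rose in both lines (1713) then outnumbered those that rose in NRK-52E and fell in NRK-49F (1085), against 2218 and 703 for independent lists, so the shortfall of shared increases was present under both scalings. Among 292 genes changed by at least 2-fold in both lines the order of the opposite classes turned: 83 rose in NRK-52E and fell in NRK-49F, 126 did the reverse, 70 rose in both and 13 fell in both.

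**Figure D4:**
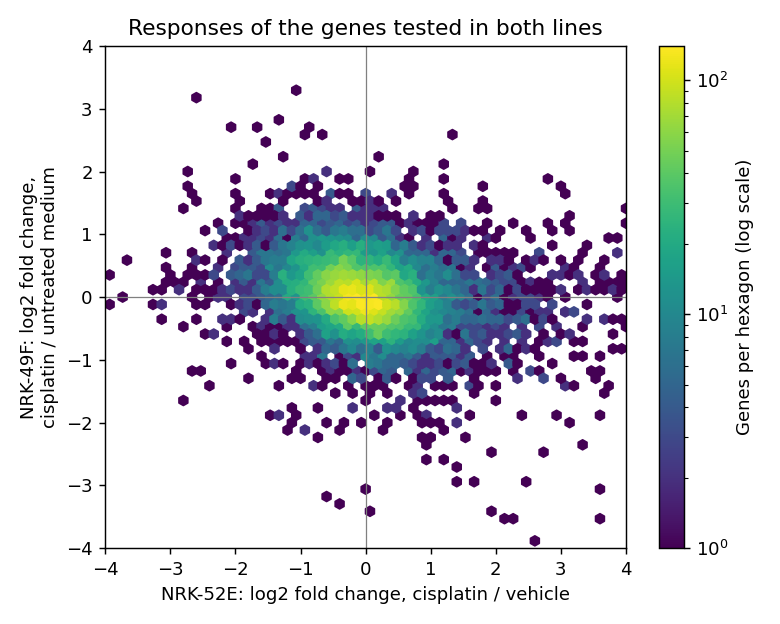
Log2 fold changes of the genes tested in both lines, for cisplatin against vehicle in NRK-52E (horizontal axis) and cisplatin medium against untreated medium in NRK-49F (vertical axis), with colour giving the number of genes per hexagon on a log scale. The cloud slopes downward (Pearson correlation -0.254 across 10937 genes), and 70 genes with a change beyond 4 on the log2 scale lie outside the axes.

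The difference of the 2 responses was tested directly in one edgeR fit of all 12 libraries. Of 13127 genes, 4447 had a higher and 4277 a lower log2 fold change in NRK-52E than in NRK-49F, and 4403 did not pass. With library size only the split was 3602 and 5196, and the median difference moved by -0.18 on the log2 scale. Genes called with opposite directions have differing responses by construction, and all 3611 passed. Of the 1854 genes that moved the same way in both lines, 993 differed in size (53.6%). Of 2897 genes called in NRK-52E but not in NRK-49F, 2353 differed between the lines (81.2%), and of 1340 called in NRK-49F alone, 1037 did (77.4%). Choosing genes by a call in only 1 line, in these same libraries, favours a pass, and 66.5% of all 13127 genes passed. The lines received different agents, the drug and a medium, so the contrast does not separate line from agent.

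ENSRNOG00000062503, which fell in NRK-52E, was at 75.6 ± 4.35 CPM in NRK-49F with untreated medium and 74.3 ± 1.64 CPM with cisplatin medium (SD, n = 3 each). Its log2 fold change there was -0.02 with a standard error of 0.05, and the difference between the responses was -4.65 (edgeR adjusted p = 8.12e-32). ENSRNOG00000046643 rose in NRK-49F as well, from 2.18 ± 0.55 to 3.5 ± 0.538 CPM (SD, n = 3 each), a log2 fold change of 0.69 with a standard error of 0.23 (edgeR adjusted p = 0.0109). Its responses differed between the lines (edgeR adjusted p = 6.46e-14). ENSRNOG00000057443 also passed the contrast (edgeR adjusted p = 1.71e-06). With 4 counts in all of NRK-52E it was not tested in that line, so no response was measured there. ENSRNOG00000009726 did not pass the contrast (edgeR adjusted p = 0.761), where 1 count in NRK-52E leaves a difference undetectable at this depth.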

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

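The tests of a trend with abundance and of NRK-52E material carried over in the medium were chosen after their results were seen.

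The responses of 8724 genes differed between the lines by the direct test of the difference, which is why they are given here, as did those of ENSRNOG00000046643, with a difference of 9.05 on the log2 scale (edgeR adjusted p = 6.46e-14), and ENSRNOG00000062503, with a difference of -4.65 (edgeR adjusted p = 8.12e-32). The value of 9.05 depends on the prior count, since NRK-52E vehicle libraries held 0 counts of that gene. Groups of 3 libraries are too small for the search for single deviating libraries.

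The first pattern is that genes called in both lines mostly moved in opposite directions. The responses were correlated within classes of genes of like mean CPM over all 12 libraries. At 1 CPM or more, r was -0.219 or lower (at most -0.203 with any library left out). A trend with this mean that both lines shared would favour shared directions and so is no explanation of opposite ones. In classes by the mean CPM of each line's own 6 libraries, median log2 fold changes went down with abundance in both lines. They were 0.255 in NRK-52E and 0.237 in NRK-49F at 1 to 10 CPM, and -0.095 and -0.157 at 100 CPM or more. The classes over all 12 libraries do not test such a trend with each line's own abundance, which could move genes of unlike abundance in opposite directions and is left open. Under 1 CPM, 29 genes (r = 0.074) were too few to tell a trend and the pattern apart. In fits without replicate 1 of the control groups, r was -0.237 over all 11077 genes, -0.228 among 8632 genes within 4-fold between the lines and -0.149 among 5946 within 2-fold, so genes enriched 4-fold in one line are not its whole cause. If cisplatin left in the medium had repeated the NRK-52E response, genes raised there would have risen in NRK-49F. Of 183 genes raised 4-fold in NRK-52E and expressed at 10 CPM in NRK-49F, 34 rose and 112 fell in NRK-49F. Their median log2 fold change was -0.342 (95% bootstrap interval -0.474 to -0.206). With library size only it was -0.142 (-0.274 to -0.006, 62 rose and 89 fell). As a set these genes did not repeat the rise, but choosing them by it restates part of the pattern. Genes enriched 4-fold in NRK-49F had a like median there, -0.32, or -0.12 with library size only. Whether carried-over cisplatin contributed is therefore not decided. Effects of fewer or dying donor cells on the medium, and the biological explanation that fibroblasts respond to it in an opposed way, were not tested.

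The second pattern is the larger number of genes detected in cisplatin-treated NRK-52E. Sequencing depth does not account for it, since the gain was 2251 genes in libraries thinned to one total (1258 unthinned with a minimum of 5 counts in place of 1). RNA of NRK-49F as the whole source is argued against by the 789 genes with 0 counts in all vehicle and at least 1 count in every cisplatin library (median 3 counts), of which 57.8% (456 genes, 95% interval 54.3 to 61.3%) had 0 counts in all NRK-49F libraries, and by the 94 genes that reached 2 CPM, of which 71 were at or under 3 counts over the untreated-medium libraries. A small NRK-49F share is not excluded for the other genes, as 79 of 102 genes expressed in NRK-49F but hardly in NRK-52E were higher with cisplatin, by a median of 0.209% of their NRK-49F level. Genomic DNA, unspliced RNA and a broader set of expressed genes were not tested and stay open.

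The third pattern is that NRK-49F in cisplatin medium lay closer to NRK-52E. NRK-52E cells or RNA carried over in the medium would bring the transcripts that only NRK-52E expresses, but the pooled gain of 77 such genes was 0.043% of their NRK-52E level (0.028 to 0.054% per library), far below the share that the increased genes would need. That share had a median of 50.7% (95% bootstrap interval 48.1 to 52.6%) over 2646 genes more highly expressed in NRK-52E, among 3351 that rose in the fit without replicate 1 of untreated medium, which had served to choose the 77 genes. A shift of the fibroblasts' own expression was not tested.

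For chance in the grouping of libraries, the 10 splits of 6 libraries are too few for a share under 0.05 in either line. In NRK-52E 1 of 10 splits, the real one, called 9536 genes and the highest other called 0, and in NRK-49F 1 of 10 called 7123 and the highest other 0. Over 100 combined splits of both lines, 1 gave 5465 genes called in both lines and the highest other 0. As each regrouped line called 0 genes, this count had to come out so and adds nothing to the separate splits. For the difference of the responses the 100 splits within the lines were drawn, unlike the combined splits above. Of these, 1 gave 8724 genes, and the highest other, 5390, kept the NRK-52E groups intact. Among the 76 splits that kept neither line's groups the highest was 0, so this count follows whether the groups of each line were kept and does not test whether the responses differ. The correlation of -0.254 was the largest in size in 1 of 100 combined splits, but the highest other was 0.253, and a split of a line other than the real one still sets 2 libraries of one treatment against 1 and so keeps part of the contrast, so chance and the pattern cannot be told apart by this count.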

How the results depend on the processing

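The alternatives for the correlation of the responses, for the genes with opposite directions and for the numbers of detected genes were added after seeing the data; the others were planned. The count of genes whose responses differed and the counts called in both lines and in opposite directions stayed within 1.5 times under 20 of 20 alternatives each, and the called genes of each line under 16 of 18. The exceptions were a required absolute log2 fold change of 1 (2795 genes in NRK-52E, 786 in NRK-49F) and the test against 1.5-fold (3883 and 1184), which ask for larger changes by construction. A like count can hold other genes. With library size only, 5527 of the 7123 genes called in NRK-49F stayed called and 46 called genes changed sign. The share that rose went from 49.9% to 75.4%. The 4 named genes kept direction and call under 11 of 11 alternatives each. With 1 library left out the counts ranged over 9166 to 9572 (NRK-52E), 6606 to 6799 (NRK-49F), 8444 to 8684 (difference), 5073 to 5410 (both lines) and 3367 to 3591 (opposite directions), and the correlation over -0.255 to -0.231. It was -0.068 with no filter and -0.302 for genes with at least 50 counts in 3 libraries, and the cause was not tested. The NRK-52E gain in detected genes was 1258 with a minimum of 5 counts.

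With the replicate number as a block the counts were 9382, 7020 and 8577, and 5316 in both lines, and it moved no count by over 1.5 times. Same-numbered libraries did not deviate together within a line (correlations of deviations -0.051 to 0.004 in NRK-52E and -0.022 to 0.021 in NRK-49F). Between the cisplatin groups of the lines each of the 3 libraries correlated best with its own number (0.019 to 0.037), but between the control groups 0 of 3 did (-0.034 to 0.002). All these values lay under the 0.1 used as the threshold for pairing, and the design names no pairing, so they do not show it. Camera, fry and the other alternatives for gene lists, and the removal of mitochondrially encoded genes, were not run, as identifiers could not be named. Depth limits genes under 0.239 to 0.31 CPM in a single library, where a count of 0 cannot show absence.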

Other observations

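Whether the gene was enriched in one line was examined after the opposite directions had been seen, and these sets were chosen after seeing the data. Enrichment was taken from replicate 1 of both control groups (at least 4-fold, at least 5 CPM), and the responses from fits without that replicate, for genes of at least 1 CPM in the responding line. Of 1106 NRK-52E-enriched genes tested in NRK-52E, 723 fell with cisplatin (65.4%) and 217 rose, with a median log2 fold change of -0.52 (95% bootstrap interval -0.58 to -0.46). In NRK-49F with cisplatin medium 796 of them were tested, and 564 rose (70.9%) and 22 fell, with a median of 0.63 (0.60 to 0.66). NRK-49F-enriched genes went the other way. In NRK-49F 445 of 759 fell (58.6%) and 129 rose, with a median of -0.32 (-0.40 to -0.24), and in NRK-52E 270 of 420 rose (64.3%) and 71 fell, with a median of 0.73 (0.56 to 0.87). A gene enriched in one line is also more abundant there, and in both lines genes of 100 CPM or more rose less often than genes of 1 to 10 CPM. Enriched genes were not compared with others of like abundance in the line, so enrichment and abundance cannot be told apart here.

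With library size only the NRK-49F median was 0.83 for NRK-52E-enriched genes (658 rose, 10 fell). It was -0.12 for NRK-49F-enriched genes, of which 232 rose and 356 fell, so this decrease was smaller under that scaling. Genes enriched in neither line had medians of -0.06 in NRK-52E and -0.01 in NRK-49F, and the latter became 0.19 with library size only. The correlation of the responses in these fits was -0.237 over all 11077 genes, -0.434 among 1397 genes enriched in either line, -0.228 among 8632 genes within 4-fold and -0.149 among 5946 genes within 2-fold.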
